A study of Mus musculus with 20 samples.

How the data were processed

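RNA from primary mouse renal tubular epithelial cells was sequenced in 20 libraries. Per the labels' protocols the cells were grown in medium with 10% serum, EGF, prostaglandin E2, triiodothyronine, hydrocortisone and epinephrine, RNA was extracted with a column kit, and libraries were made from total RNA with a directional (strand-marking) kit. Each sample was placed in its group (het or KO, control or LPS+IFNγ) and given its replicate number from its title. The labels also give an animal ID to each library. 8 animals gave libraries of 1 genotype and animals 5 and 7 are listed under both. The labels tie each library to an animal but do not say how the cultures were split, so p-values measure the spread between these libraries.

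The deposited table holds 1 column of counts per library and 55891 Ensembl gene IDs, with no line that names no gene and 0 per-sample columns left unused. The submitters' processing notes name FastQC 0.11.9, Salmon 1.10.2, R 4.4.1 and DESeq2 1.45.3 and the genome build GRCm39, without saying what each did. Salmon gives estimated counts, and the deposited values are whole numbers, so they were treated as estimated counts, and rounding them to whole numbers before the tests changed none. How transcripts were summed to genes, the strand setting and any filter are not given in the sources used here. Gene symbols came from an annotation of another build (GENCODE M21, GRCm38), which was used for names and for the order of neighbouring genes only, so no coordinates are given. A symbol was found for 51425 IDs (92.0%), which hold 98.8% of the counts. Of 503 listed symbols 501 were found, and the listed gene Ptprg was not analysed here. Genes with near-identical copies (the Gbp, Tgtp, Oas1, Ifit3, Saa and H2-Q families) can share reads, so their single values are uncertain.

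Total counts per library were 12899528 to 20411411. Exact 95% intervals and the limit allowed by a count of 0 (3 counts of the total) were computed for Ptprz1. The libraries carry no molecular identifiers as far as the sources say, so these intervals cover counting error only. TMM factors ran from 0.939 to 1.13.

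Counts were analysed in R 4.3.3. The main test was edgeR 4.0.16 (TMM scaling, filterByExpr on the 4 groups, robust quasi-likelihood fit, quasi-likelihood F test) with all 20 libraries in 1 model of 4 group means and no block, so that the groups share 1 estimate of the spread. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. The SE of a log2 fold change was taken as its size divided by the square root of F. The comparisons were LPS+IFNγ against control in het and in KO cells, KO against het in each state, and the difference between the responses. Ptprz1 was tested with an exact two-sided permutation test of CPM, KO against het, in each state. A fold is not given where a group had 3 counts or fewer in all its libraries together.

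In addition 21 gene lists were tested with camera (limma 3.58.1, voom weights, preset correlation 0.01, at least 3 measured members), two-sided, adjusted over the lists of a comparison. They were interferon-gamma response, type I interferon-stimulated genes, MHC class I and MHC class II antigen presentation, NF-kB targets with cytokines and chemokines, tubular injury and repair, proximal tubule, loop of Henle to collecting duct, fatty acid oxidation and mitochondrial metabolism, apoptosis, pyroptosis and necroptosis, cell cycle, Wnt targets, extracellular matrix with TGF-beta, oxidative and endoplasmic reticulum stress, Ptprz1 ligands and the CSF1R axis, the genes next to Ptprz1 on chromosome 6, and markers of leukocytes, fibroblasts, endothelium and podocytes. Some genes are on more than 1 list, for example Tap1 and Psmb9 (interferon-gamma and MHC class I), Vcam1 (NF-kB and injury), Col1a1 (matrix and fibroblast) and Csf1r (leukocyte and CSF1R axis). Camera's preset correlation can be too low for genes that vary together, so the adjusted p with a correlation estimated per list is given beside the calls that are lost with it.

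The groups, the tests, the lists, the alternatives and the rule for named genes were fixed before the data were examined. By that rule the text names, among called genes with a mean log2 CPM of at least 1 and a symbol that is not a predicted name, the 8 with the highest and the 8 with the lowest fold change. Where fewer than 5 pass in a direction it also names the genes with the lowest p up to 5. Ptprz1, Il34, Csf1 and Csf1r are named in every comparison, with up to 3 members of each list by lowest p. Some genes that the rule names are not reported here.

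The animal ID ties control and stimulated libraries of 8 animals within a genotype. Deviations from the group means correlated at −0.331 to 0.652 between the libraries of an animal, above 0.1 in 8 of 10 pairs, and 10 of 20 libraries matched the other library of their animal best. The alternatives were another scaling (DESeq2's size factors), no filter or a filter of CPM of at least 1 in 10 libraries, DESeq2 1.42.0, limma-voom, only the libraries compared, an added minimum log2 fold change of 1, leaving out each library in turn, leaving out the animals listed under both genotypes, and the animal or the replicate number as a block or random effect. Added after seeing the data were fits without the 4 libraries of KO replicate 4 and het replicate 5, without the 4 libraries of het replicates 1 and 4, combinations of either with each other or with other alternatives, and list tests with a block. Means of a list per library used log2(CPM + 0.5).

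Each step was tested on simulated data with up to 200 genes changed 2-fold or 4-fold. In the 20-library design the test recovered 46.0% of 2-fold and 81.8% of 4-fold changes for the response of het cells (14393 genes, 8 wrongly called), 51.0% and 83.0% for KO cells (14364 genes, 6 wrongly called), 41.4% and 77.8% for genotype in control cells (14383 genes, 3 wrongly called), 53.1% and 86.6% for genotype in stimulated cells (14369 genes, 7 wrongly called) and 18.4% and 59.2% for the difference in response (14377 genes, 3 wrongly called). In the 16-library design it recovered 39.4% and 75.0% for the response of het cells (14446 genes) and 46.5% and 82.8% for KO cells (14422 genes). For genotype it recovered 47% and 74% in control cells (14414 genes) and 36.1% and 68% in stimulated cells (14406 genes). For the difference in response it recovered 20.4% and 55.1% (14418 genes). The simulated libraries followed their labels, which 4 of the real ones did not.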

Results

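Primary renal tubular epithelial cells from mice carrying a targeted Ptprz1 allele were sequenced as 20 libraries in 4 groups of 5. Ptprz1 encodes a receptor-type protein tyrosine phosphatase. Heterozygous (het) cells, which the series takes as the Ptprz1-expressing comparator, and knockout (KO) cells were each left untreated (control) or exposed for 24 h to LPS at 100 ng/mL together with IFNγ at 10 ng/mL, a combination that activates Toll-like receptor 4 and interferon-gamma signalling. Total counts per library ran from 12899528 in KO control replicate 5 to 20411411 in het control replicate 1, with a median of 17431039. The extracellular matrix gene Fn1 held 0.337 to 2.37% of the counts of a library and the 10 most abundant genes held 5.39 to 8.23%. The labels name 10 animals, and animals 5 and 7 are listed under both genotypes. Values are log2 fold changes ± SE from edgeR's quasi-likelihood test, or CPM as mean ± SD with n libraries per group.

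Ptprz1 (ENSMUSG00000068748) itself was close to the detection limit in every library. In control cells its level was 0.0866 ± 0.163 CPM in KO and 0.0817 ± 0.118 CPM in het libraries (SD, n = 5 each), from 7 counts over the group in each genotype. In stimulated cells it was 0.103 ± 0.198 CPM in KO and 0.107 ± 0.104 CPM in het libraries (SD, n = 5 each), from 8 and 9 counts. The difference between genotypes did not exceed the spread between libraries in either state (exact two-sided permutation test, p = 1 and p = 1 over 252 permutations). The highest values came from the libraries labelled KO control replicate 4, with 6 counts, and KO LPS+IFNγ replicate 4, with 7 counts, both from animal 8. A count of 0, found in 11 libraries, allows up to 0.147 to 0.233 CPM by counting error, so a loss of Ptprz1 expression was not detectable at this depth. Which part of the gene the KO allele lacks is not given in the sources used here, so counts in KO libraries need not stand for an intact transcript, and the genotype labels could not be checked with this gene.

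Genes induced by interferon-gamma followed the stimulation label in 16 libraries and went against it in 4. Nos2 (inducible nitric oxide synthase) reached 1255 to 3564 CPM in 8 of the 10 stimulated libraries and at most 0.219 CPM in 8 of the 10 controls. In the libraries labelled control of KO replicate 4 and het replicate 5, Nos2 stood at 202 and 82.8 CPM and the guanylate-binding protein gene Gbp2 at 1491 and 482 CPM. In the libraries labelled stimulated of the same replicates, Nos2 had no counts and Gbp2 stood at 13 and 12.9 CPM, against 3394 to 11517 CPM in the other 8. The peptide transporter gene Tap1 showed the same pattern, at 277 and 167 CPM in the controls so labelled and at 17.5 and 19.3 CPM in the stimulated ones. These 4 libraries come from animals 8 and 4. All libraries were kept under their labels in the first account of each comparison, and "the library labelled" is meant wherever a direction is given for a group that holds them. Nos2, Gbp2 and Tap1 were singled out here after their values were seen.

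**Figure D1:**
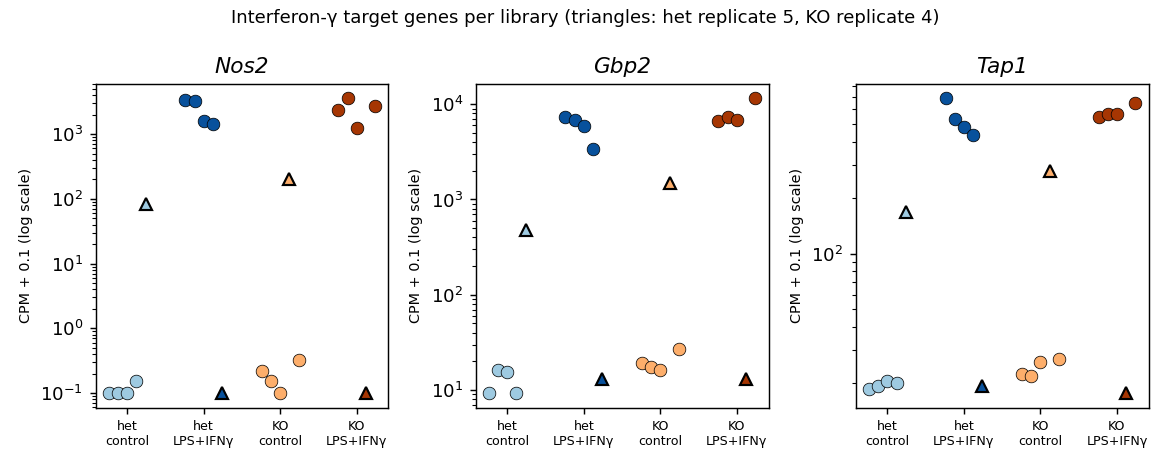
CPM plus 0.1 on a log axis for Nos2, Gbp2 and Tap1 in each of the 20 libraries, by group, with 1 point per library. Triangles mark het replicate 5 and KO replicate 4, whose controls lie above the other 8 controls and whose stimulated libraries lie at the level of the controls, for example Nos2 at 202 CPM in KO control replicate 4 and at 0 in KO LPS+IFNγ replicate 4.

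The first question was how het cells respond to LPS+IFNγ. With the 20 libraries as labelled, 4 groups of immune genes were raised relative to other genes. All 34 measured interferon-gamma response genes, all 30 type I interferon-stimulated genes, 19 of 20 MHC class I genes and 35 of 36 NF-kB targets had positive fold changes (camera, Benjamini-Hochberg adjusted p = 1.25e-12, 2.06e-12, 2.78e-11 and 5.12e-13, and adjusted p = 0.426 with an estimated correlation for each). Isg20, an interferon-induced exonuclease, differed by 2.74 ± 0.56, the antiviral GTPase gene Mx1 by 6.99 ± 1.42 and Il15, a cytokine for lymphocytes, by 2.52 ± 0.52 (adjusted p = 0.105 for each, n = 5 per group, not past the threshold). Gbp11 and Batf2 had adjusted p values of the same size and went from 0.0111 ± 0.0249 CPM each to 7.73 ± 7.88 and 22.7 ± 33.1 CPM. On the lower side Gamt, for creatine synthesis, was at −1.1 ± 0.24, Acadm, for oxidation of medium-chain fatty acids, at −0.63 ± 0.15, Slc30a5 at −0.31 ± 0.074, Pccb at −0.95 ± 0.23 and Klhl12 at −0.35 ± 0.085 (adjusted p = 0.105 for each). Csf1, the macrophage growth factor, was at 1.64 ± 0.48 (adjusted p = 0.136), Il34, which shares the receptor Csf1r with it and also binds Ptprz1, at 0.21 ± 0.19 (adjusted p = 0.680), and Csf1r at −1.05 ± 0.90 (adjusted p = 0.670).

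No single gene passed the 0.05 threshold in that comparison (edgeR quasi-likelihood test, 14568 genes, 1981 at an unadjusted p under 0.05 where 728 come by chance). DESeq2 called 483 genes, 435 higher and 48 lower, and limma-voom called 0. Adjusted over the list alone, 29 interferon-gamma response genes, 30 type I genes, 13 MHC class I genes and 27 NF-kB targets passed, all higher. Leaving out the library labelled het LPS+IFNγ replicate 5 gave 744 genes.

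Further lists moved in het cells. The pyroptosis and necroptosis list, with Mlkl at 3.11 ± 0.76 and Il18 at 1.97 ± 0.51, was raised, with positive fold changes in 12 of 13 members of which none passed over all genes (adjusted p = 1.35e-05, adjusted p = 0.426 with an estimated correlation), and 10 passed adjusted over the list alone. The apoptosis list was raised, with positive fold changes in 22 of 31 members and Cflar at 0.93 ± 0.22 (adjusted p = 0.00550, adjusted p = 0.426 with an estimated correlation). Cflar encodes an inhibitor of caspase 8. The stress list was raised, with positive fold changes in 19 of 24 members and the heme oxygenase gene Hmox1 at 2.23 ± 0.62 and Ddit3 at 1.65 ± 0.47 (adjusted p = 0.00428, adjusted p = 0.454 with an estimated correlation). MHC class II genes had positive fold changes in 10 of 10 (adjusted p = 0.0109, adjusted p = 0.557 with an estimated correlation). In each of these 3 lists 4 members passed adjusted over the list alone. All 32 cell cycle genes had positive fold changes, with Cdt1 at 1.32 ± 0.51 (adjusted p = 0.000639, adjusted p = 0.661 with an estimated correlation), and 0 of them passed adjusted over the list alone (1 at an unadjusted p under 0.05). The fatty acid oxidation list was lower in 20 of 24 members (adjusted p = 0.0145, adjusted p = 0.501 with an estimated correlation), with 1 member up and 1 down adjusted over the list alone. Its median was −0.12 and its mean 0.16, the latter owing to Acod1, which makes itaconate. Single libraries carried several of these calls. Leaving out het LPS+IFNγ replicate 1 gave an adjusted p of 0.108 for apoptosis, 0.0595 for stress and 0.193 for the cell cycle, and leaving out replicate 4 gave 0.0981 for MHC class II. The cell cycle also lost its call without het control replicate 4 (0.164), and fatty acid oxidation without het control replicate 1 (0.374) or 4 (0.0702) or het LPS+IFNγ replicate 2 (0.117) or 3 (0.107).

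The lists for tubular injury and repair (adjusted p = 0.274), proximal tubule (0.416), loop of Henle to collecting duct (0.768), Wnt targets (0.840), extracellular matrix and TGF-beta (0.741), leukocyte markers (0.594), fibroblast markers (0.220), endothelial markers (0.496), podocyte markers (0.485), the genes next to Ptprz1 on chromosome 6 (0.122) and the Ptprz1 ligands with the CSF1R axis (0.489) did not pass in het cells.

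The same question in KO cells, as labelled, gave the same 4 leading groups. Positive fold changes were found in 34 of 34 interferon-gamma response genes, 30 of 30 type I genes, 19 of 20 MHC class I genes and 33 of 36 NF-kB targets (camera adjusted p = 3.13e-14, 2.92e-13, 2.92e-13 and 2.88e-13). MHC class II genes (0.000188), pyroptosis and necroptosis genes (1.90e-05) and stress genes (0.000100) were also raised, and each of the 7 lists had an adjusted p = 0.371 with an estimated correlation. Wars, a tryptophan tRNA ligase gene, differed by 2.71 ± 0.57, Sharpin by 0.41 ± 0.089, Ifit2 by 4.86 ± 1.08 and Panx1 by 0.90 ± 0.20, and Gbp11 went from 0.0250 ± 0.0559 to 11.2 ± 11.5 CPM (adjusted p = 0.321 for each, not past the threshold). On the lower side Ttc25 was at −0.99 ± 0.25, Fgf18 at −1.80 ± 0.48, the intermediate filament gene Synm at −3.54 ± 0.97, the oxytocin receptor gene Oxtr at −4.17 ± 1.2 and Stard7 at −0.29 ± 0.085 (adjusted p = 0.321 for each). Csf1 was at 0.95 ± 0.47, Il34 at 0.0071 ± 0.19 and Csf1r at −1.5 ± 0.93 (adjusted p = 0.579, 0.998 and 0.717).

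By edgeR 0 genes passed in KO cells, with 1307 at an unadjusted p under 0.05, while DESeq2 called 115 (110 higher, 5 lower) and limma-voom 0. Adjusted over the list alone, 14 interferon-gamma response, 27 type I, 10 MHC class I, 5 MHC class II, 12 NF-kB, 6 pyroptosis and 2 stress genes passed. Leaving out the library labelled KO LPS+IFNγ replicate 4 gave 152 genes. The Wnt target list (adjusted p = 0.104) and the apoptosis list (0.131) did not pass.

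Because 4 libraries went against their labels in the very genes under study, the stimulus comparisons were repeated without them, with 4 libraries per group. These libraries were chosen after the data were seen and by the outcome itself, so the counts that follow describe the other 16 libraries and are not independent evidence of a response. In het cells 829 genes rose and 217 fell after LPS+IFNγ, and in KO cells 704 rose and 139 fell (edgeR, adjusted p under 0.05, 14630 genes). Nos2 went from 0.0128 ± 0.0256 to 2399 ± 1006 CPM in het and from 0.0974 ± 0.0939 to 2475 ± 961 CPM in KO cells. The chemokine gene Cxcl9 reached 265 ± 279 and 214 ± 63.0 CPM (SD, n = 4 each). Tap1 rose by 4.78 ± 0.15 in het and 4.59 ± 0.15 in KO cells, the immunoproteasome gene Psmb9 by 7.36 ± 0.30 and 7.55 ± 0.31, and Gbp3 by 8.84 ± 0.35 and 8.56 ± 0.34 (adjusted p = 1.92e-09 or lower for the 3 genes in each genotype). Other genes with the highest fold changes were Gbp10, Gbp4, Gbp5 and Apol6 in both genotypes, Acod1 and Ifi206 in het and Ciita and Gbp6 in KO cells. Several of these had 3 counts or fewer over the controls of a genotype, so no fold is given.

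Group by group in these 16 libraries, 34 of 34 interferon-gamma response genes rose in het and 33 in KO cells, with 30 and 29 of 30 type I genes and 19 and 19 of 20 MHC class I genes. Stat2, for interferon signalling, rose by 3.87 ± 0.22 and 3.81 ± 0.22, and Parp14 by 5.74 ± 0.43 and 5.92 ± 0.43. MHC class II genes rose in 7 of 10 in each genotype, with H2-Ab1 at 5.04 ± 0.72 and 5.22 ± 0.71. NF-kB targets and chemokines rose in 28 and 25 of 36, with the monocyte chemokine genes Ccl2 at 8.09 ± 0.69 and 7.30 ± 0.67 and Ccl7 at 8.81 ± 0.70 and 7.28 ± 0.65. Pyroptosis and necroptosis genes rose in 9 and 7 of 13, among them the inflammatory caspase gene Casp4 by 3.66 ± 0.30 and 3.43 ± 0.30 and Mlkl by 3.78 ± 0.35 and 3.37 ± 0.35. Adjusted over the list alone, the counts were 34 and 34 interferon-gamma response, 30 and 30 type I, 19 and 19 MHC class I, 33 and 31 NF-kB and 10 and 10 pyroptosis genes. With an estimated correlation the adjusted p was 2.57e-05 in het and 1.90e-05 in KO cells for the interferon-gamma list, 5.46e-05 and 2.89e-05 for MHC class I, 0.0223 and 0.0191 for the type I and for the pyroptosis list, and 0.0293 and 0.0360 for NF-kB targets. Apoptosis (adjusted p = 0.0590 and 0.164 with an estimated correlation), stress (0.235 and 0.164) and MHC class II genes (0.334 and 0.203) passed with the preset correlation and with fry, which tests whether the genes of a list move one way on balance (fry adjusted p = 0.000521 and 0.0108, 0.0200 and 0.0108, 0.0456 and 0.0159). Cell cycle genes (adjusted p = 0.000750, adjusted p = 0.655 with an estimated correlation) and, as lower, fatty acid oxidation genes (0.0171 and 0.463) passed in het cells with the preset correlation alone. With fry alone the genes next to Ptprz1 were lower in het cells (fry adjusted p = 0.0234) and Wnt targets higher in KO cells (0.0332). With the animal as a block and an estimated correlation in 12 libraries the interferon-gamma list passed in both genotypes (adjusted p = 0.0363 and 0.0365) and NF-kB targets in het cells (adjusted p = 0.0431 and 0.0622), while MHC class I (0.0984 and 0.0734), type I (0.0984 and 0.0960) and pyroptosis genes (0.0984 and 0.108) did not.

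Csf1 rose by 2.16 ± 0.24 in het and 1.72 ± 0.24 in KO cells of the 16 libraries (adjusted p = 3.05e-05 and 0.000256). In CPM it went from 136 ± 36.3 to 605 ± 161 and from 154 ± 24.6 to 505 ± 133 (SD, n = 4). Il34, at 0.25 ± 0.20 and 0.057 ± 0.20, and Csf1r, at −1.5 ± 0.91 and −2.84 ± 0.98, did not pass. The adhesion molecule gene Vcam1 rose by 4.4 ± 0.68 and 4.31 ± 0.67, the endoplasmic reticulum stress gene Ddit3 by 1.99 ± 0.39 and 1.97 ± 0.39, the Wnt target Axin2 by 2.06 ± 0.52 and 2.68 ± 0.53, and the necroptosis kinase gene Ripk1 by 0.61 ± 0.075 and 0.57 ± 0.075. Hmox1 and the adhesion receptor gene Cd44 rose in het cells, by 2.62 ± 0.56 and 2.03 ± 0.36, and stood at 1.59 ± 0.54 and 0.93 ± 0.35 in KO cells without passing (the test of the difference in response gave adjusted p = 1.00 for Cd44 and 1.00 for Hmox1). Among the genes that fell, Oxtr dropped by 5.24 ± 1.1 in het and 4.73 ± 1.05 in KO cells and the calcium-binding protein gene Ncald by 2.40 ± 0.30 and 2.48 ± 0.30. H19 (−4.29 ± 1.22), Frem2 (−3.58 ± 0.86), Slc5a7 (−3.20 ± 0.76), Il1r1 (−2.81 ± 0.79), Tenm4 (−2.78 ± 0.49) and Mylk (−2.48 ± 0.63) fell in het cells. Synm (−4.17 ± 0.89), Elmod1 (−2.97 ± 0.77), Zim1 (−2.63 ± 0.44), Kif27 (−2.48 ± 0.56), Scube3 (−2.33 ± 0.63) and Ppp2r2b (−2.33 ± 0.49) fell in KO cells. Acadm fell in het cells (−0.81 ± 0.13), while 0 of 13 proximal tubule genes and 0 of 32 cell cycle genes passed in either genotype by edgeR (2 and 4 of them at an unadjusted p under 0.05 in het cells, 0 and 2 in KO cells).

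Of the genes that rose in the 16 libraries 576 were shared by both genotypes, where 39.9 would be shared by independent lists of those sizes, and of those that fell 65 were shared, against 2.06. Both genotypes had the same stimulus and their libraries were kept for following the labels. An overlap above these values was therefore to be foreseen and does not test whether the responses are alike. No gene was called in opposite directions. Across the 14630 genes the fold changes of het and KO cells, which share no library, correlated at r = 0.851 and rho = 0.626. Genes are not independent replicates, and animals 5 and 7 each have a library in both sets. Among the 1248 genes called in either genotype 1236 had the same sign. Leaving out also the animals listed under both genotypes gave 604 and 462 genes in 12 libraries, and with the animal as a block 2388 and 1672. The 16 libraries without animals 1 and 9 gave 623 and 1960 genes. In the 16 libraries DESeq2 called 1675 and 1321 genes.

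**Figure D2:**
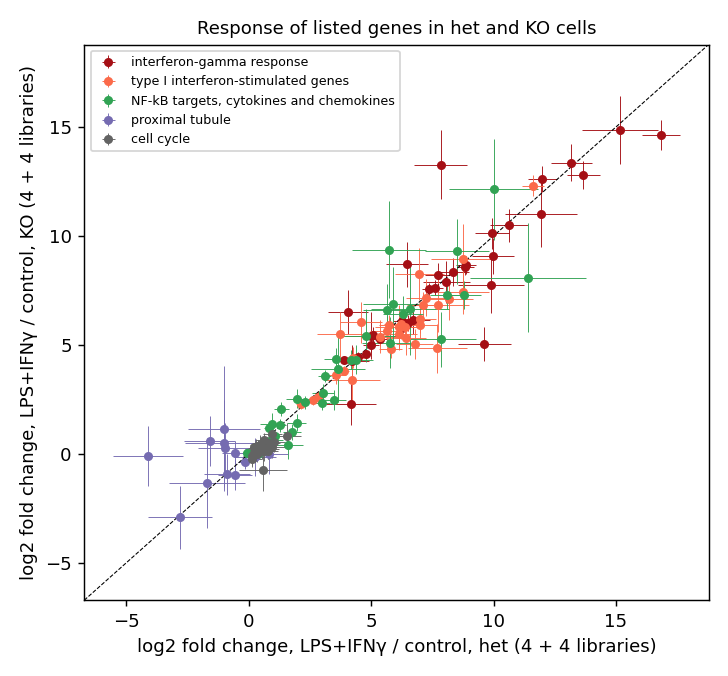
log2 fold change after LPS+IFNγ in KO cells (vertical axis) against het cells (horizontal axis) for the genes of 5 lists in 16 libraries, with bars of 1 SE and a dashed line of equality. The 4 libraries that went against their labels are left out, which was decided after the data were seen. Tap1 lies at 4.78 in het and 4.59 in KO cells, and genes with few or no counts in the controls lie far out at values that depend on the prior count.

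The second question was whether unstimulated KO and het cells differ. As labelled, the KO group was lower in proximal tubule genes and in leukocyte markers. Of 12 proximal tubule genes 11 were lower, among them the water channel gene Aqp1 at −4.59 ± 1.30, the amino acid transporter gene Slc3a1 at −3.98 ± 1.08 and the transcription factor gene Hnf4a at −5.65 ± 1.78 (camera adjusted p = 0.0158, adjusted p = 0.982 with an estimated correlation), and 4 passed adjusted over the list alone. All 7 leukocyte markers were lower, with Lyz2 at −3.94 ± 1.48 and Cd68 at −2.40 ± 1.04 (adjusted p = 0.0368, adjusted p = 0.982 with an estimated correlation). Fatty acid oxidation genes were lower in 19 of 24, with Acadm at −0.42 ± 0.15 and Acaa1b at −1.74 ± 0.60 (adjusted p = 0.000104, adjusted p = 0.936 with an estimated correlation), and matrix genes were higher in 20 of 28, though Tgfbr1 at −0.24 ± 0.15 and Itgb6 at −2.33 ± 1.46 were lower (adjusted p = 0.00142, adjusted p = 0.982 with an estimated correlation).

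These group differences rested on the het libraries of replicates 1 and 4, from animals 1 and 9. Hnf4a was at 174 and 77.1 CPM in those controls and at most 2.91 CPM in every library of the other animals, and Lyz2 at 43.2 and 214 CPM against at most 9.76. Leaving out replicate 1 or replicate 4 alone ended the calls of the proximal tubule (adjusted p = 0.193 and 0.158), leukocyte (0.193 and 0.700) and matrix lists (0.215 and 0.158). Without these 2 animals, a choice made after the data were seen, the adjusted p was 0.870 for the proximal tubule list and 0.870 for leukocyte markers, both with the opposite sign, 0.870 for fatty acid oxidation, and 0.0109 for matrix genes, then lower in KO cells. Fibroblast markers, which had not passed, were then lower in KO cells too (adjusted p = 0.000798). That fit keeps the libraries that went against their labels, 1 of 3 het and 1 of 5 KO controls. With these left out as well (2 het and 4 KO controls), matrix genes and fibroblast markers were again lower in KO cells (adjusted p = 0.00369 for each), interferon-gamma response (0.00369), MHC class I (0.00877) and type I genes (0.00988) were higher, and the proximal tubule (0.856) and leukocyte lists (0.655) did not pass and had the first sign again. With an estimated correlation no list passed in either fit (lowest adjusted p = 0.825 and 0.896). The 2 het controls of the last fit come from animals 2 and 7, and animal 7 is listed under both genotypes. The control of animal 7 had the highest list means (log2 level) of all libraries for fibroblast markers (6.155) and matrix genes (8.737). That of animal 2 (4.429 and 8.282) lay within the range of the KO controls (4.071 to 4.706 and 7.789 to 8.490). The lower fibroblast and matrix calls there therefore lean on 1 library of uncertain genotype.

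Single genes with the lowest p in unstimulated cells were, on the higher side in KO, Med15 at 0.32 ± 0.091, Ccdc151 at 0.99 ± 0.30, Oser1 at 0.29 ± 0.091 and Ebf1 at 0.98 ± 0.36. On the lower side were Ndufa2, of respiratory complex I, at −0.27 ± 0.072, Calml4 at −5.37 ± 1.47, Aqp1, the prostaglandin receptor gene Ptger3 at −2.29 ± 0.66 and Amn at −5.85 ± 1.71. None passed (adjusted p = 0.999 for each). Il34 was at 0.41 ± 0.19, Csf1 at 0.52 ± 0.47 and Csf1r at −0.77 ± 0.90 (adjusted p = 0.999 for each). edgeR called 0 genes, with 499 at an unadjusted p under 0.05, limma-voom called 0 and DESeq2 called 2. These were Calml4, which DESeq2 gave an adjusted p of 0.0383, and ENSMUSG00000121501, which has no symbol in the names used here. The latter ran from 0 to 1483 counts per library, and its log2 fold change was 18.9 by DESeq2 but 4.30 by edgeR (quasi-likelihood test, unadjusted p = 0.268). The female-specific transcript Xist was high in 3 of 5 het and 1 of 5 KO controls. Interferon-gamma response genes (adjusted p = 0.565), the genes next to Ptprz1 (0.975) and the Ptprz1 ligands (0.202) did not pass as lists. Without the 4 libraries that went against their labels 7 lists passed, the 4 named above in the same directions, interferon-gamma genes (adjusted p = 0.00834) and fibroblast markers (0.00834), both higher in KO cells by camera, and stress genes, lower (0.0447), each with an adjusted p = 0.665 with an estimated correlation. By edgeR, however, only 4 of 12 fibroblast markers had positive fold changes there, with a median of −0.21. The list means (log2 level) of the het controls kept ran from 1.70 in replicate 1 to 6.155 in replicate 3 (animal 7). Those of the KO controls kept lay between, at 4.07 to 4.71. The direction for fibroblast markers therefore depends on the measure and is not settled.

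The third question was whether stimulated KO and het cells differ. KO cells were lower in 11 of 12 proximal tubule genes, with Hnf4a at −4.68 ± 1.76, and in 29 of 32 cell cycle genes, with the replication licensing gene Cdt1 at −1.1 ± 0.51 and cyclin D1 (Ccnd1) at −2.09 ± 0.97 (camera adjusted p = 0.00966 and 0.00966). They were higher in 10 of 12 fibroblast and pericyte markers, with Pdgfra at 0.93 ± 0.52, and in 21 of 28 matrix genes, with Col1a2 at 1.60 ± 1.22 (adjusted p = 0.00714 and 0.0445). Each of the 4 lists had an adjusted p = 0.745 with an estimated correlation, and in each 0 members passed adjusted over the list alone by edgeR (1, 2, 0 and 0 at an unadjusted p under 0.05). Leukocyte markers were lower in 7 of 7, with Cd68 at −2.82 ± 1.05, and did not pass (adjusted p = 0.0706). Without the 4 libraries that went against their labels 10 of 10 members measured in that fit were lower and the list passed (adjusted p = 0.00526, adjusted p = 0.459 with an estimated correlation), with 8 members past the threshold adjusted over the list alone. Groups of 4 let the filter keep genes expressed in only 4 libraries, where groups of 5 need 5. Members high only in the 4 libraries of het replicates 1 and 4 can enter that way, so the larger count adds no support. The leukocyte difference lay in het LPS+IFNγ replicates 1 and 4, from animals 1 and 9. Their list means (log2 level) were 2.075 and 4.085, against at most 1.049 in the 16 libraries of the other animals. Without these 2 animals, and with the reversed libraries kept, Lyz2 turned to 0.69 in stimulated cells.

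The cell cycle difference hung on single libraries. KO LPS+IFNγ replicate 5 stood apart as low in that list (mean log2 level 3.81 against 4.67 to 5.01 in the other 4), and without it the adjusted p was 0.806 with the opposite sign, as it was without het LPS+IFNγ replicate 1 (0.762). Without het LPS+IFNγ replicate 2 or 3 it was 0.0970 and 0.149. The proximal tubule call ended without het LPS+IFNγ replicate 4 (0.114), the fibroblast call without het replicate 1 (0.0961) or 4 (0.0513), and the matrix call without het replicate 1 (0.0961) or 4 (0.455) or KO replicate 3 (0.0710) or 4 (0.167). Leaving out only the library labelled het LPS+IFNγ replicate 5, which went against its label, gave 13 lists, with interferon-gamma response (4.43e-05) and type I genes (4.18e-09) lower in KO cells. Leaving out only KO LPS+IFNγ replicate 4, which did likewise, gave 11 lists, with both higher (2.68e-07 and 0.000374).

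None of the 4 list calls held in its first direction without animals 1 and 9. The adjusted p was 0.547 for the proximal tubule, 0.157 for the cell cycle and, with the opposite sign, 0.634 for the fibroblast and 0.00599 for the matrix list. In the same fit 10 lists passed with the preset correlation, 9 of them higher in KO cells, led by NF-kB targets (adjusted p = 1.65e-06) and type I interferon genes (2.96e-05), and 0 with an estimated correlation (lowest adjusted p = 0.592). The libraries that went against their labels remain in it, as 1 of 3 het but 1 of 5 KO libraries, so libraries with low interferon genes weigh more in the het group. With these left out as well (2 het and 4 KO libraries), 9 lists passed with the preset correlation. Higher in KO cells were 7 of them, among them MHC class II (4.38e-10), interferon-gamma response (2.17e-07), NF-kB targets (4.61e-06) and type I genes (7.57e-05), and lower were the cell cycle (3.45e-08) and matrix lists (0.00782). None of the 21 lists passed there with an estimated correlation (lowest adjusted p = 0.291). In that fit 1 of the 2 het libraries (replicate 3, animal 5) and KO replicate 3 (animal 7) come from animals listed under both genotypes. Het replicate 3 had the lowest list means there for interferon-gamma response (8.16), NF-kB (4.894) and MHC class II (2.362). Het replicate 2 lay within the KO range for NF-kB (5.538 against 5.383 to 5.764) and below it for MHC class II (2.592 against 3.190 to 4.945). Leaving out KO LPS+IFNγ replicate 5 from that fit gave the cell cycle list an adjusted p of 0.00262 (2 het and 3 KO libraries), and leaving it out with the reversed libraries alone gave 0.191. Without the animals listed under both genotypes the cell cycle list had an adjusted p of 0.132.

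In stimulated cells the lowest p among single genes belonged to Bcat2 at 0.42 ± 0.11, Zfp771 at 0.59 ± 0.19, Nr4a2 at 0.71 ± 0.24, Hps6 at 0.43 ± 0.15 and Calhm5 at 1.46 ± 0.53. On the lower side they were the imprinted gene Usp29 at −1.68 ± 0.47, Odf2l at −0.45 ± 0.13, Malt1 at −0.59 ± 0.16, Isca2 at −0.37 ± 0.11 and Glrx at −1.99 ± 0.59. Csf1 was at −0.17 ± 0.47, Il34 at 0.21 ± 0.19 and Csf1r at −1.23 ± 0.92. None of these passed (adjusted p = 1.000 for each). Inflammatory cytokine genes with lower values in KO were Il1a at −3.48 ± 1.49, Ccl20 at −3.23 ± 1.43, Il1b at −3.33 ± 1.5 and Csf3 at −3.17 ± 1.44, also not past the threshold. The NF-kB list, which holds Il1a, Ccl20 and Il1b, was highest in het LPS+IFNγ replicates 1 and 4, from animals 1 and 9. Its mean log2 level there was 6.54 and 7.04, against at most 5.76 in the other stimulated libraries. edgeR called 0 genes, with 366 at an unadjusted p under 0.05, and DESeq2 and limma-voom called 0. Neither the interferon-gamma response list (adjusted p = 0.642) nor the NF-kB list (0.253) passed. Without the 4 libraries that went against their labels the first was higher (adjusted p = 0.00526) and the second, with type I genes, lower in KO cells (adjusted p = 0.00193 and 0.00526). In that fit 12 lists passed, also the 4 lists first called and leukocyte markers, in the same directions, MHC class I (0.0216), MHC class II (0.00511) and Wnt genes (0.0216) as higher and tubular injury genes (0.00420) as lower in KO cells, each with an adjusted p = 0.459 with an estimated correlation. Without animals 1 and 9 NF-kB targets and type I genes were instead higher in KO cells, whether the reversed libraries were kept or left out as well. High Xist occurred in 2 of 5 libraries of each genotype.

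**Figure D3:**
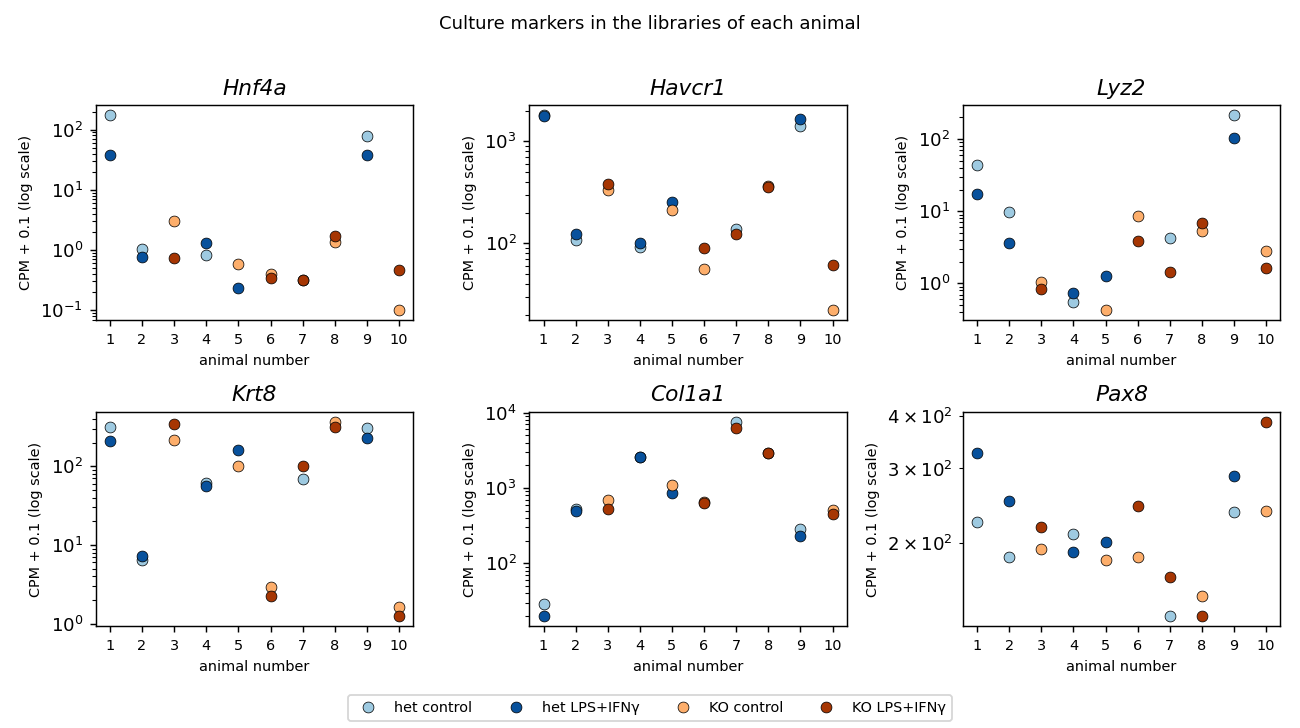
CPM plus 0.1 on a log axis for Hnf4a, Havcr1, Lyz2, Krt8, Col1a1 and Pax8 in each library (vertical axis), by animal number (horizontal axis), with colours for the group. Both libraries of animal 1 and of animal 9 lie highest for Hnf4a, from 38.3 to 174 CPM, and animals 5 and 7 carry colours of both genotypes.

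The last question was whether the response to LPS+IFNγ differs between KO and het cells. No gene passed (edgeR, 0 genes, with 138 at an unadjusted p under 0.05, limma-voom 0, DESeq2 1 gene, ENSMUSG00000121501). That gene, with 0 to 1483 counts per library, was at −21.8 by DESeq2 but at −7.12 by edgeR (quasi-likelihood test, unadjusted p = 0.0951). The lowest p belonged to Zfp358 at 0.33 ± 0.10, the extracellular superoxide dismutase gene Sod3 at 3.61 ± 1.15, Ndufa2 at 0.31 ± 0.10, Lgi2 at 3.12 ± 1.03 and Ptger3 at 2.73 ± 0.91, and, on the lower side, Med15 at −0.40 ± 0.13, Ttc25 at −1.08 ± 0.36, Cnot4 at −0.39 ± 0.13 and Tjap1 at −0.37 ± 0.13 (adjusted p = 1.000 for each). Csf1 was at −0.69 ± 0.66, Il34 at −0.20 ± 0.26 and Csf1r at −0.45 ± 1.27. The cell cycle list responded less in KO cells, with negative differences in 30 of 32 members, such as Cenpe at −0.63 ± 0.50 (camera adjusted p = 0.00574, adjusted p = 0.946 with an estimated correlation), and 0 members passed adjusted over the list alone by edgeR (0 at an unadjusted p under 0.05). Again KO LPS+IFNγ replicate 5 stood low in that list, and without it the adjusted p was 0.605. The call was also lost without het LPS+IFNγ replicate 1 (0.833), 2 (0.0586) or 3 (0.134), het control replicate 2 (0.226) or 4 (0.714), or KO control replicate 4 (0.492). With the animal as a block in 12 libraries its adjusted p was 8.21e-05 (adjusted p = 0.767 with an estimated correlation), without animals 1 and 9 it was 0.160, and without these and the reversed libraries 0.00901 (adjusted p = 0.827 with an estimated correlation). The interferon-gamma response, type I interferon and NF-kB lists did not differ in response past the threshold (adjusted p = 0.674, 0.674 and 0.718). Leaving out only the library labelled het LPS+IFNγ replicate 5, which went against its label, gave each a lower response in KO cells (camera adjusted p = 0.000344, 0.000117 and 0.000513). The reversed KO libraries stayed in that fit and lessen the KO response. Without animals 1 and 9, 4 lists had a higher response in KO cells with the preset correlation, NF-kB targets (adjusted p = 0.00441), Wnt targets (0.00441), stress genes (0.0122) and MHC class II genes (0.0282), and 0 with an estimated correlation (lowest adjusted p = 0.869). That fit too keeps the reversed libraries, as 1 of 3 in each het and 1 of 5 in each KO group, which lessens the het response more. With these left out as well, NF-kB targets (0.0724) and stress genes (0.104) did not pass, while Wnt targets (0.0162), MHC class II genes (0.0324) and fibroblast markers (0.0137) had a higher response in KO cells with the preset correlation and none with an estimated one (lowest adjusted p = 0.688). There 1 het library in each state comes from an animal listed under both genotypes (animal 7 in controls, animal 5 in stimulated cells).

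Without the 4 libraries that went against their labels the 3 genotype comparisons still gave 0 genes each by edgeR, DESeq2 and limma-voom (774, 787 and 224 genes at an unadjusted p under 0.05 by edgeR, where 732 come by chance). For the 1248 genes called in either genotype the 95% interval of the difference in response (normal approximation) had a median half-width of 0.665 on the log2 scale. These genes were picked by their response, so this value need not hold for other genes. In simulated data of this design the test of the difference recovered 20.4% of 2-fold and 55.1% of 4-fold changes. The 0 calls therefore do not exclude differences of that size.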

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

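Among the tests of this part, those written before the result was seen are the correlation of 2 animals with the others, the level of their interferon genes, the first test of animal IDs, the distal gene test of a smaller fibroblast share and the count of leukocyte markers, and the mixing test, the 50-gene ID test, the Ptprz1 test of genotype labels, the genotype and leukocyte tests of proximal tubule genes and the counts over other splits, by called genes and by unadjusted p, were chosen after it was seen.

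Single libraries lay far from the other 4 of their group by Dixon's statistic (gap over range), which by chance happens in about 1 of 20 groups, or 4.6 of the 92 series tested. The library labelled het control replicate 5 stood high in the list means for interferon-gamma response (0.92; mean log2 level 5.47 against 1.41 to 1.73), MHC class I (0.933), apoptosis (0.713) and pyroptosis (0.714), and het LPS+IFNγ replicate 5 stood low for interferon-gamma response (0.909; 1.40 against 8.16 to 8.84) and MHC class I (0.942). The library labelled KO control replicate 4 stood high for interferon-gamma response (0.906; 6.71 against 1.58 to 2.06), MHC class I (0.843), MHC class II (0.94), NF-kB targets (0.843), apoptosis (0.855), pyroptosis (0.763), cell cycle (0.737) and Wnt targets (0.78). KO LPS+IFNγ replicate 4 stood low for interferon-gamma response (0.952; 1.66 against 8.46 to 8.81), type I genes (0.773), MHC class I (0.894), NF-kB targets (0.861), fatty acid oxidation (0.715), apoptosis (0.766), pyroptosis (0.826) and stress genes (0.736). Of 46 genes followed for this, chosen after the data were seen, 8 had such a library in het control, 9 in het LPS+IFNγ, 15 in KO control and 14 in KO LPS+IFNγ, against 9.2 expected over all 184 series, and it was replicate 5 in 7 and 9 and replicate 4 in 15 and 13 of them.

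Ptprz1 itself was highest in both libraries of KO replicate 4, at 0.375 CPM in the control (0.844) against 0 to 0.0584, and at 0.453 CPM in the stimulated library (0.867) against 0 to 0.0602. The cell cycle list was low in KO LPS+IFNγ replicate 5 (0.718; 3.81 against 4.67 to 5.01), and without that library it did not pass for genotype in stimulated cells (adjusted p 0.806) or for the difference in response (0.605). The difference in response between genotypes passed for the cell cycle list (camera adjusted p 0.00574), whose call is lost with an estimated correlation.

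The 2 libraries of animal 4 (het replicate 5) and of animal 8 (KO replicate 4) went against their stimulation labels. Over 14180 genes outside the lists, the labelled difference of these animals correlated at r = −0.635 and −0.709 with the mean of the 6 other animals, where those 6 gave 0.667 to 0.855 among themselves, which is what libraries carrying each other's label would show. Stimulated RNA mixed into a control would leave the stimulated library high, and 0 of 34 interferon-gamma genes in either library labelled stimulated reached the lowest of the other 8. An exchange with a response of the usual size is argued against too, since 33 and 30 of the 34 genes in the libraries labelled control lay below the other 8 stimulated libraries while 29 and 33 lay above the other 8 controls. An exchange of the labels with a weaker or shorter stimulation stays open as a hypothesis, no biological explanation was tested, and no label was changed.

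Animals 5 and 7 are listed under both genotypes. If 1 ID of each were wrong, the libraries should not resemble each other, and the first test (all genes) placed 1 of 4 libraries with its ID, which by its own bound spoke for a wrong ID, but it placed only 9 of 16 other libraries correctly and so decides little. On 50 genes chosen in the other animals, among them sex-linked genes, a test chosen after that result, 4 of 4 libraries matched their ID, as they did on 100 and 200 genes, which argues against a wrong ID, although the libraries of the other animals placed correctly fell from 16 to 14 and 11 of 16 as genes were added. An animal has 1 genotype. If each ID stands for a single animal and is right, 1 library of each carries a wrong genotype label. That library then lies in the wrong group in every comparison that uses it, the responses within each genotype included. Ptprz1 could not test this or tell which library it is. Its highest count in any library was 7, and the part of the gene that the allele lacks is not given. Whether the IDs stand for something other than single animals stays open.

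Proximal tubule genes and leukocyte markers were high in the 4 libraries of het replicates 1 and 4, and genotype alone is argued against, since 2 of the 4 het animals with an unambiguous ID lay within the range of the KO libraries for the proximal tubule list. Of the tested proximal tubule genes 41.7% (among them Ggt1, Hnf4a, Slc3a1 and Cubn) were higher in each of the 4 libraries than in all 16 others, against 4.60% of all genes. That test was written after the bound first set (10 genes) was given up once 5 of 12 were seen. The 4 libraries were set apart after these genes were seen to be high in them. The share therefore restates the pattern and decides nothing about leukocytes in the culture as its cause. A smaller share of fibroblast-like cells stays open. In each of the 4 libraries 7 of 12 fibroblast markers and 13 of 28 matrix genes were lower, which goes with it. On the other side 0% of 13 distal genes were higher than in all others, which by the bound written beforehand spoke against it. That bound was later set aside as wrong for genes that vary widely elsewhere (Cdh1 from 0.365 to 201 CPM), and the distal list mean (2.70 to 2.81) lay above 13 of the 16 other libraries. A smaller share should also have raised podocyte and endothelial markers. That 0 of 8 and 0 of 9 were higher than in all others decides little, for the reason given for distal genes. The podocyte list mean (3.50 to 4.84) lay on both sides of the median of the others (4.51) and does not decide either. The endothelial list mean (0.771 to 1.29) lay below the median of the others (1.73), which speaks against a smaller share. This holds unless the fibroblast-like cells carry endothelial markers too, which was not tested. For the leukocyte markers, 6 of 7 were higher (Adgre1, Cd68, Itgam, Itgax, Fcer1g and Lyz2, but not Csf1r). This count restates the pattern that raised the question, so some leukocytes in those cultures stay a possibility that it cannot test. A different starting mix of tubule cells stays open and untested.

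Other splits of the libraries tested whether chance can be excluded. With 20 libraries the real split called 0 genes in each comparison, so all 50 of the 50 drawn splits were as large by construction, which says nothing about chance (highest others 2340 for het response, 62 for KO response, 0 and 0 for genotype, 1 for the difference). By genes at an unadjusted p under 0.05, 4 of 50 splits were as large as the 1981 of the het response (highest other 4670.0), 5 as the 1307 of the KO response (2712), 17 and 41 as the 499 and 366 for genotype (2105 and 2313) and 48 as the 138 for the difference (3140.0), so chance could not be excluded. Only 50 of 126 possible splits of each 2 groups were drawn. The split with 2340 genes set both libraries of animals 1 and 9, with het LPS+IFNγ replicate 3, against the other het libraries, which points to a structure of the samples. In 16 libraries the het response gave 1046 genes and 2 of 35 splits were as large, the other being that of animals 1 and 9 with 3223 genes, a structure again (with the animal as a block in 12 libraries 2388 genes were called). Of the 8 splits that part all 3 animals with both libraries, as the real one does, the highest other gave 0 genes in each genotype, but 8 splits are too few for a share under 0.05, and the 27 others keep both libraries of at least 1 animal together. The KO response gave 843 genes, 1 of 35 splits was as large and the highest other gave 0. Because the 16 libraries were kept by the response that these splits test, neither count decides about chance. For genotype all 35 of 35 splits in each state, and for the difference in response 50 of 50, were as large as the real 0 by construction (highest others 0, 0 and 2), and by genes at an unadjusted p under 0.05, 12 and 16 of 35 and 42 of 50 were as large as the real 774, 787 and 224.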

How the results depend on the processing

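The fits without the libraries of KO replicate 4 and het replicate 5 (alone or with other changes), without those of het replicates 1 and 4 (likewise), and the blocked list tests were chosen after the result was seen, and the others were planned. As labelled, 0 genes were called in each of the 5 comparisons by edgeR (1981, 1307, 499, 366 and 138 at an unadjusted p under 0.05), and so they were in all 5 under the other scaling, no filter, the stricter filter, limma-voom, without the animals listed under both genotypes, with the replicate block by number or as a random effect, and without het replicates 1 and 4. Only the libraries compared (not run for the difference in response) and the replicate block by animal (not run for genotype) also gave 0. DESeq2 called 483 (het response), 115 (KO response), 2 (genotype in controls), 0 and 1 (difference in response) genes, and 457 and 114 of the first 2 sets were also called in the 16-library fit. Leaving out 1 library at a time gave 0 to 744 genes in het and 0 to 152 in KO cells, the non-zero values without het LPS+IFNγ replicate 5 and without KO LPS+IFNγ replicate 4 alone, and 0 in the genotype comparisons; 687 and 152 of these genes were also called in 16 libraries. The cause was not tested.

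Without the 4 reversed libraries het and KO cells gave 1046 and 843 genes, 653 and 570 with a minimum log2 fold change of 1, with DESeq2 1675 and 1321, with limma-voom 912 and 727, and with the animal as a random effect 3142 and 2057 (replicate block, animal correlation 0.577). Without also the animals of both genotypes there were 604 and 462, and with the replicate block by animal 2388 and 1672. The 16 libraries without het replicates 1 and 4 gave 623 and 1960 (cause not tested). Leaving out a further library from the 16 gave 792 to 1123 and 583 to 719, and no genotype comparison called a gene under any of these.

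The lists past the threshold numbered 10 (het response), 7 (KO response), 4 and 4 (genotype in control and stimulated cells) and 1 (difference). Leaving out 1 library gave 7 to 11, 7 to 9, 1 to 7, 2 to 13 and 0 to 9 lists, and the cell cycle list in stimulated cells ran from an adjusted p of 1.94e-06 without het LPS+IFNγ replicate 4 to 0.806, with the sign turned, without KO LPS+IFNγ replicate 5 (also turned, 0.762, without het LPS+IFNγ replicate 1). Genotype gave 7 lists in stimulated cells without a filter, and in controls 2 with the stricter filter and 2 with only the libraries compared. With an estimated correlation and with fry they were 0 in all 5 (lowest fry adjusted p 0.228, 0.259, 0.985, 0.765 and 0.976), and in 16 libraries 5 in het cells and 0, 0 and 0 for genotype and the difference with an estimated correlation, and with fry 9, 9, 0, 0 and 0. In 16 libraries with the preset correlation genotype gave 7 and 12 lists. The replicate block by number on all 20 libraries gave 12, 8 and 3 lists for the het response, the KO response and the difference, adding proximal tubule (0.0046) and fibroblast markers (0.00939), matrix genes (0.0361), and Wnt targets (0.0158) with fibroblast markers (0.0348). The replicate block by animal in 12 libraries gave 12 for the KO response and 2 for the difference, and with an estimated correlation 2 (interferon-gamma and NF-kB), 1 (interferon-gamma) and 0. Without het replicates 1 and 4 genotype gave 2 lists in control and 10 in stimulated cells and the difference 4, and with an estimated correlation all 5 gave 0. Without the reversed libraries as well the lists were 11, 8, 5, 9 and 4, and with an estimated correlation 4, 4, 0, 0 and 0. The fit without het replicates 1 and 4 turned 5 list results round, in 4 lists: matrix genes (0.0109 in control, 0.00599 in stimulated cells), fibroblast markers (0.634), leukocyte markers (0.87) and proximal tubule (0.87), with an estimated correlation 0.825, 0.592, 0.897, 0.978 and 0.978, and also Hnf4a in controls (log2 fold change 0.66), Lyz2 in stimulated cells (0.69) and Csf1 in stimulated cells (0.20). Without the reversed libraries as well it turned matrix genes (0.00369 and 0.00782, with an estimated correlation 0.896 and 0.409), Hnf4a in controls (0.68) and Il34 in stimulated cells (−0.055). The cause of the other moves was not tested. The block changed no call of a gene on all 20 libraries.

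Values near 0 changed sign. When 1 library was left out, Csf1 between genotypes ran from −0.44 to 0.087 in stimulated cells, above 0 without het LPS+IFNγ replicate 4, and from −0.089 to 0.77 in controls, below 0 without KO control replicate 4. Il34 in the KO response (0.0071) went to −0.0018 with the other scaling, −0.013 without a filter, −0.0017 with DESeq2, −0.0095 with limma-voom, −0.012 with only the libraries compared, −0.013 with the replicate block by number and −0.11 to 0.091 when 1 library was left out. In the difference in response Il34 went to 0.037 with the replicate block by animal, without the reversed libraries and the animals listed under both genotypes. The alternatives were run for 46 of the genes, each in the comparisons chosen for it, and not for the other named genes. Counting each of these genes and each list once per alternative, 2219 values kept direction and side of the threshold, 371 passed only in the alternative, 186 only as first analysed and 37 changed sign. The cause of these was not tested. Depth limits Ptprz1, at 0 to 7 counts per library.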

Other observations

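The genes and groups in this part were chosen after their values were seen, and none of their counts was planned.

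Levels of cell type markers differed widely between the cultures of different animals. Both libraries of animals 1 and 9 had the highest levels of the proximal tubule transporter gene Slc6a18, at 427 and 549.9 CPM in control and 147 and 259 CPM in stimulated cells, against 0.730 to 25.5 CPM in every other library. The injury marker Havcr1 (kidney injury molecule) was at 1804 and 1427 CPM in their controls and 1770.0 and 1639 CPM in their stimulated libraries, against 22 to 385 CPM elsewhere. In the same 4 libraries 13 of 28 matrix genes and 7 of 12 fibroblast markers were lower than in all 16 others. Collagen gene Col1a1 ranged from 19.6 CPM in the stimulated library of animal 1 to 7620.0 CPM in the control of animal 7. The libraries of animals 2, 6 and 10 had low epithelial genes, with the cadherin gene Cdh1 at 0.365 to 1.72 CPM, Epcam at 0.146 to 0.935 CPM and the keratin gene Krt8 at 1.13 to 7.15 CPM, while Pax8, a transcription factor of the renal epithelium, stood at 185 to 388 CPM. Elsewhere Cdh1 was at 18.8 to 201 CPM and Krt8 at 56.2 to 371 CPM.

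The neighbouring imprinted genes Peg3 and Zim1 separated the 8 animals listed under 1 genotype. Averaged per animal, Peg3 was at 412 to 764 CPM in 4 het and 252 to 382 CPM in 4 KO animals, and Zim1 at 8.34 to 25.2 and 4.25 to 6.31 CPM, while Usp29 overlapped (6.09 to 19.7 and 3.61 to 6.95 CPM). Over 12382 genes 64 (0.517%) did not overlap between these animals, 41 lower and 23 higher in KO, where chance gives 2.86%, so such a separation is no evidence of a genotype effect by itself.

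Sex-linked genes differed between animals and fell unevenly over the groups. Xist stood at 209.9 to 395 CPM in both libraries of animals 2, 4, 6 and 7 and at no more than 1.43 CPM in the others, where the Y-linked gene Ddx3y stood at 64.7 to 154 CPM. High Xist occurred in 3 of 5 het controls, 2 of 5 het LPS+IFNγ, 1 of 5 KO controls and 2 of 5 KO LPS+IFNγ libraries. The 2 libraries of each of the 10 animals matched in these genes, those of KO replicate 4 and het replicate 5 included.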
